A study of Mus musculus with 8 samples.

How the data were processed

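Gene expression was measured by RNA sequencing in macrophages taken from the peritoneum of C57BL/6 mice after injection of thioglycolate, an irritant that draws such cells into the cavity. The labels list 8 samples in 4 groups of 2, formed by genotype (wild type or Ptpn1 knockout) and treatment (mock or IL-10 at 100 ng/ml for 4 h). Cells had adhered to plastic for 24 h, and RNA was taken with TRIzol and prepared by the standard Illumina protocol, per the labels' protocols. RSEM, Bowtie and the mm9 mouse genome are named in the submitters' processing notes, without versions. Their roles, the gene annotation, the normalization and any filter on genes are not given in the sources used here.

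The deposited table lists 11996 genes with 1 value for each of the 4 groups, so the authors gave a normalized expression signal per group and the table used here carries no column per sample. No value had a match to a single library, and each is printed as the authors' mean, without an SD or an n. The submitters named the data as CPM, and no other unit is stated. The values are nevertheless not CPM: each column sums to 26705598. All values are multiples of 0.5, and 36.6 to 37.2% of a column's values end in 0.5, as means of 2 whole numbers do. The highest value, 362618, is the same in all columns and is shared by 8 genes in the wild-type mock column, 6 in wild type with IL-10, 7 in the knockout mock column and 5 in the knockout with IL-10. Values of this kind arise when libraries are forced onto a common distribution and then averaged, which is an inference from the numbers and is recorded in no header or label. Such a step removes differences in sequencing depth and any shift common to most genes, and it caps the most abundant genes: Ctss was listed at the highest value in all 4 columns, so no difference could be seen in it. For the 146 genes with a mean signal above 20000, neighbouring ranks lie far apart, and a small move in rank gives a large move in signal. Depth per library is unknown, so no counting interval or floor is given.

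The tests fixed before the data were examined (limma-trend fits of 5 comparisons, gene set tests, a replicate block, leave-one-out fits) need values per library and were not run. No p-value is given for a difference between groups. In their place each comparison is a log2 ratio of signals, with the planned pseudocount of 1 ppm of the column total (26.7 units of signal) added to both, so that ratios of low genes are understated. The planned filter, a mean over the 4 columns of at least 1 ppm, kept 11400 genes. The limit of 2-fold (a log2 ratio of at least 1 in size) replaced the test's threshold after the structure of the table was known. The 5 comparisons were IL-10 against mock in each genotype, knockout against wild type under each treatment, and the difference between the genotypes' IL-10 log2 ratios.

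The 14 gene lists and 12 cell type marker lists were fixed before the data were examined. For each list with at least 3 kept members, the median log2 ratio was set among those of 10000 random lists of the same size, drawn from 20 bins of mean signal so as to match the members. Its percentile describes these 4 columns and is not a test. The rule for naming genes was also fixed beforehand, with size in place of the p-value: Ptpn1, Socs3, Bcl3, Nfil3, Il4ra, Il1rn, Tnf, Stat3 and Il10ra, among others, in every comparison; the 6 largest differences of at least 2-fold in each direction with at least 5 ppm (134 units) in the higher group, or the 3 largest where fewer than 3 passed; and up to 3 members per list with the largest differences. The planned condition that libraries do not overlap could not be applied. Some members were left out of the text, a few items are not reported here, and genes named outside the rule are said to be so. The rule took no members of the cell type marker lists as such, so single markers named in the text were chosen after their values were seen, except Col3a1 and Lyz2, which were among the largest differences. Where a name stood on more than 1 row, which held for 38 names, the row with the highest mean signal stood for it in the lists.

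Agreement between comparisons was described by Pearson's and Spearman's coefficients across genes and by the overlap of genes past a limit, beside the overlap of independent lists. The pairs compared share no column, but all columns share the authors' normalization. Whether the mock and IL-10 cells of a genotype came from the same mice is not stated in the labels used here. Genes are not independent replicates, so no p-value is attached.

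Coordinates are those of the deposited table and were not checked to span whole genes. They carry mm9, the build in the submitters' processing notes. Of the 11797 gene identifiers also present in GENCODE M21 on GRCm38, 484 had a start within 1000 bases of their GRCm38 start, and no coordinate from that annotation is printed. GENCODE M21 was used only for the length and GC content of each gene's longest transcript, available for 11797 of the 11996 genes.

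The alternatives run were pseudocounts of 0.25 and 4 ppm, no filter, a filter of 5 ppm and quantile normalization of the log2 values. Added after the data were seen were a trimmed-mean scaling, a limit of 1.5-fold, leaving out genes above 20000 units, leaving out the monocyte, mesothelial and fibroblast markers, and subtracting a running median of 401 genes over transcript length. The counting and list steps were tested on simulated data made from the real gene levels with a log2 noise SD of 0.15 per column. For the IL-10 response in wild type, over 11400 genes, 100% of 50 genes planted at 3-fold, 42% of 50 planted at 2-fold and 0% of 50 planted at 1.5-fold were listed at 2-fold or more, as were 0% of 11200 genes left as they were. Genes were planted only at 5 ppm or more, and the noise SD was an assumed value, equal at all levels. No replicates were available to set it. These percentages are therefore not error rates of the 2-fold limit in the real columns, least of all among low genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.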

Results

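RNA of thioglycolate-elicited peritoneal macrophages from wild-type mice and from mice lacking Ptpn1 was sequenced after mock treatment or 4 h with IL-10 at 100 ng/ml. Ptpn1 encodes PTP1B, a phosphatase that removes phosphate from tyrosines of receptors and JAK kinases, and IL-10 is an anti-inflammatory cytokine that acts on macrophages through JAK1, TYK2 and the transcription factor STAT3. The comparisons ask how macrophages of each genotype responded to IL-10, how the genotypes differed under each treatment, and whether the IL-10 response differed between them. Each of the 4 groups had 2 samples in the labels, and the values are 1 authors' mean signal per gene and group for 11996 genes. No value per sample was analysed here, so no difference below could be set against the spread between replicates, and sequencing depth is unknown. Differences are log2 ratios of signal with a pseudocount, over the 11400 genes that passed the filter on low values. The single markers of cell types named below were chosen after their values were seen, except Col3a1 and Lyz2, which the rule for named genes also took.

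Ptpn1 (ENSMUSG00000027540; mm9 chromosome 2, 167757872 to 167804885, plus strand) was listed at 4961 units in wild type and 3837 in the knockout under mock treatment, a log2 ratio of -0.37. With IL-10 its signal was 6736 units in wild type and 5392 in the knockout, a log2 ratio of -0.32. The gene's signal was thus not absent from the knockout columns. Neither the part of the gene that each value counts nor the deleted part is given in the sources used here. This level is therefore a weak check of the genotype labels. Of the 500 genes nearest in mean signal, 91.4% had a smaller or equal mock difference in size. Ptpn1 was itself listed higher with IL-10 in both genotypes, with log2 ratios of 0.44 in wild type and 0.49 in the knockout.

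In wild-type macrophages more genes were higher than lower with IL-10. Socs3, the feedback inhibitor of cytokine signalling that STAT3 induces, was listed at 381 units under mock and 3925 with IL-10, a log2 ratio of 3.28. Cd244, a receptor of the SLAM family, was listed at 29 and 740 units, the endothelin receptor Ednrb at 426 and 4058, the TNF family ligand Tnfsf14 at 5 and 202, Fgl2 at 753 and 4363, and Lrg1 at 26 and 253. Of the 11400 genes, 53 were at least 2-fold higher and 2 at least 2-fold lower. The lower genes were Msn, at 183406 and 75723 units, and the potassium channel gene Kcnj2, at 1314 and 555. The next largest difference downward, in the costimulatory receptor gene Cd28, was a log2 ratio of -0.93. Msn lies above 20000 units, where a small move in rank shifts the signal widely.

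The fixed list of IL-10 and STAT3 response genes had a median log2 ratio of 0.47 in wild type, at percentile 100 of 10000 random lists matched on signal. Of its 24 kept members, 5 were at least 2-fold higher, Socs3, Il4ra and Bcl3 among them, and none was 2-fold lower. Il4ra, the IL-4 receptor alpha chain, stood at 2057 and 4637 units, Bcl3, an atypical inhibitor of NF-kB, at 825 and 1862, and the repressor Nfil3 at 370 and 630. Stat3 itself was listed at 4330 and 8651 units (log2 ratio 0.99), whereas Il10ra and Il1rn had log2 ratios of -0.14 and 0.36. Among Fc and scavenger receptors the inhibitory Fcgr2b was the 1 of 17 kept members at least 2-fold higher, at 5784 and 13145 units. Of the alternative activation list, Arg1, which encodes arginase 1, was 1 of 15 past the limit, at 951 and 3187 units. Of the 26 inflammatory cytokine and chemokine genes fixed beforehand 8 were not listed, so the list says nothing of those. Of the 17 kept, 2 were at least 2-fold higher, Ccl4 at 206.5 and 462 units and Il1b at 9.5 and 48, a low signal. None was 2-fold lower, and Tnf had a log2 ratio of 0.30. Their median was 0.11, or 0.03 with the trend over transcript length subtracted. The labels name no inflammatory stimulus in culture. Cd209a and Lck, fixed markers of dendritic cells and T cells, were higher with IL-10. Cd209a stood at 6 and 61.5 units and Lck at 11.5 and 105. The other listed dendritic cell marker, Zbtb46, stood at 101 and 84 units. The other listed T cell markers were Il7r, at 32926 and 34645.5 units, and Cd5, at 15.5 and 11. Most T cell markers were not listed.

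In knockout macrophages the same leading genes were higher with IL-10, and more genes passed the limit. Of 11400 genes, 100 were at least 2-fold higher and 2 at least 2-fold lower. Tnfsf14 was listed at 8 and 454 units, Cd244 at 51.5 and 1014, Socs3 at 432 and 5021, Ednrb at 700.0 and 6577, Fgl2 at 1241 and 8438, and Casp4, which encodes an inflammatory caspase, at 450.0 and 2666. The lower genes past the limit were Kcnj2, at 1132 and 394 units, and Zhx2, at 49 and 1, which lay below the level for named genes and is given after its values were seen. Its row overlaps that of another gene. Rnf144b stood at 1610 and 792 units and the fractalkine receptor gene Cx3cr1 at 238 and 106. The IL-10 and STAT3 list had a median of 0.56 with 6 of 24 members at least 2-fold higher, Stat3 among them at 3678 and 8460 units. The inflammatory cytokine and chemokine list had a median of 0.30 at percentile 100, or 0.29 with the length trend subtracted, and 2 of 17 members were at least 2-fold higher. The median of its members' differences between the genotypes' responses was 0.05 at percentile 85.5, or 0.10 with that trend subtracted, with 9 of 17 above 0. The interferon lists stood further from 0 than in wild type. Of the interferon-gamma list, 10 of 21 members were at least 2-fold higher in the knockout against 0 of 21 in wild type, with medians of 0.74 and 0.33. Of the type I interferon list, 6 of 28 were at least 2-fold higher in the knockout and 1 of 28 (Zbp1, a sensor of Z-form nucleic acids) in wild type, with medians of 0.51 and 0.19. All 4 medians lay at percentile 100. No member of either list was 2-fold lower. The 5 kept monocyte markers had medians of 0.41 in the knockout and 0.15 in wild type, at percentiles 99.73 and 94.4.

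The responses of both genotypes, which come from separate columns, had a Pearson's r of 0.73 and a Spearman's rho of 0.53 across genes. Both were lower for longer transcripts (Spearman's rho -0.36 in wild type and -0.13 in the knockout), which can add to the agreement. Of the 53 and 100 genes at least 2-fold higher, 49 were shared, where independent lists would share 0.465. At 1.5-fold, 27 lower genes were shared between the 47 of wild type and the 92 of the knockout, against 0.379 for independent lists.

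**Figure D1:**
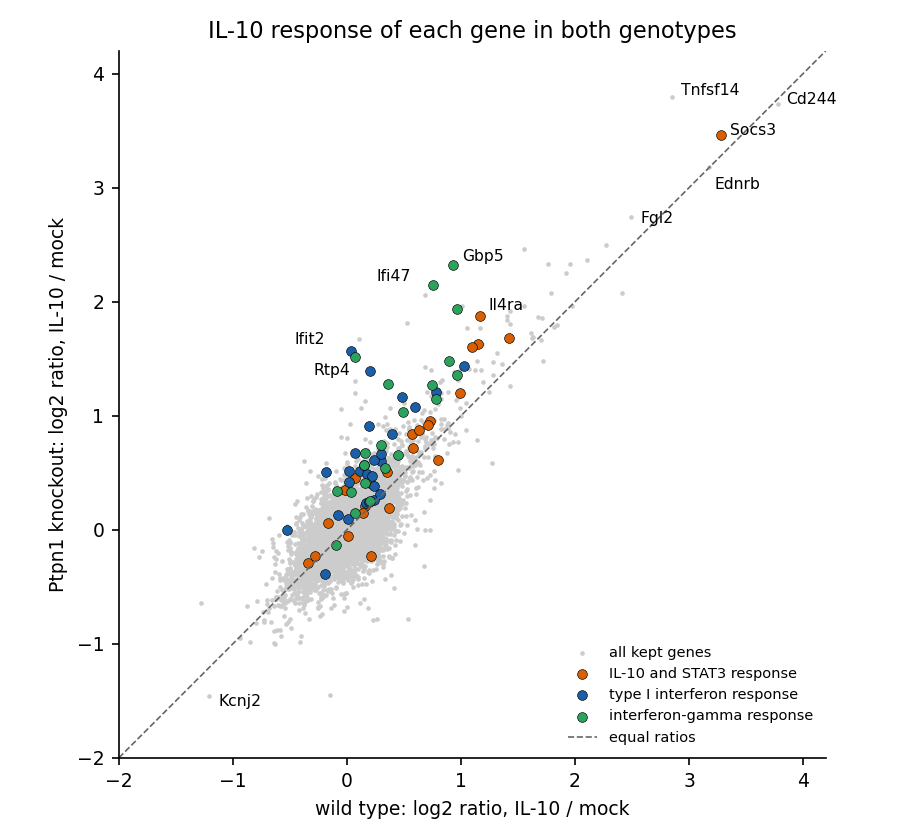
Log2 ratio of IL-10 to mock signal in wild type (horizontal axis) and in Ptpn1 knockout macrophages (vertical axis), 1 point per kept gene, with 3 fixed gene lists in colour and a dashed line of equal ratios. Socs3 lies at 3.28 and 3.46, and the interferon list members Ifit2 (0.04 and 1.57), Rtp4 (0.21 and 1.39) and Ifi47 (0.76 and 2.15) lie above the line.

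Under mock treatment the knockout had higher signal of interferon-stimulated genes than wild type. Irf7, a transcription factor that drives interferon production, was listed at 625 units in wild type and 2124 in the knockout, a log2 ratio of 1.72. Ifi27l2a stood at 395 and 1623 units, Oas1g, of the family of enzymes that sense double-stranded RNA, at 123 and 455, the receptor transporter gene Rtp4 at 114 and 468, Ifit3 at 23.5 and 159, and the chemokine gene Ccl8 at 46.5 and 239. All 28 kept members of the type I interferon list were above 0, with 10 at least 2-fold higher, a median of 0.80 and a percentile of 100. The interferon-gamma list had a median of 0.38 with 1 of 21 members at least 2-fold higher (Gbp6, 36 and 114 units). Monocyte markers were higher too: the median of 5 kept markers was 0.61 at percentile 99.99, with Ly6c2 at 15 and 100 units and Ccr2 at 371 and 582. The list of MHC class II and costimulation genes had a median of 0.46, with H2-Eb1 at 1789 and 3052 units, H2-Ab1 at 2699 and 4434 and H2-Aa at 4405 and 6758, and none of the 12 reached 2-fold. Of the alternative activation list, Chi3l3, a chitinase-like protein gene, was the 1 of 15 past the limit, at 574 and 1482 units.

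Among genes lower in the mock-treated knockout, the ubiquitin ligase gene Mid1 (mm9 chromosome X, 166413191 to 166421906) was listed at 2600 units in wild type and 581 in the knockout, a log2 ratio of -2.11. Col6a5 stood at 181 and 57 units, Col3a1 at 4587 and 1963, and Mgll, which encodes a lipase of monoacylglycerols, at 1179 and 515. Lrp1 (mm9 chromosome 10, 126983451 to 126986973; 226524 and 54367 units) and Lyz2 (362618 and 136852 units) were also among the 6 largest, and both lie in the range where rank steps are wide, with Lyz2 at the highest value of the wild-type mock column. Markers of mesothelial cells and fibroblasts, cells that line or support the peritoneum, had a median of -0.58 over 8 kept members, at percentile 0, with Col3a1 among them and Col1a1 at 5847 and 3791 units. Gata6, the transcription factor of resident peritoneal macrophages, was listed at 700.0 and 408 units, whereas Cxcl13, also a resident macrophage marker, stood at 944 and 1765. Of the 7 resident markers 3 were above 0 and 4 below, with a median of -0.29, or -0.09 with the trend over transcript length subtracted. Macrophage markers as a group had a median of -0.04. In all, 37 genes were at least 2-fold higher and 12 at least 2-fold lower. Across genes the mock log2 ratio was lower for longer transcripts (Spearman's rho -0.53). The count depended on low genes: it was 57 and 18 with a pseudocount of 0.25 ppm, 18 and 5 with 4 ppm, and 25 and 6 with the filter at 5 ppm.

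**Figure D2:**
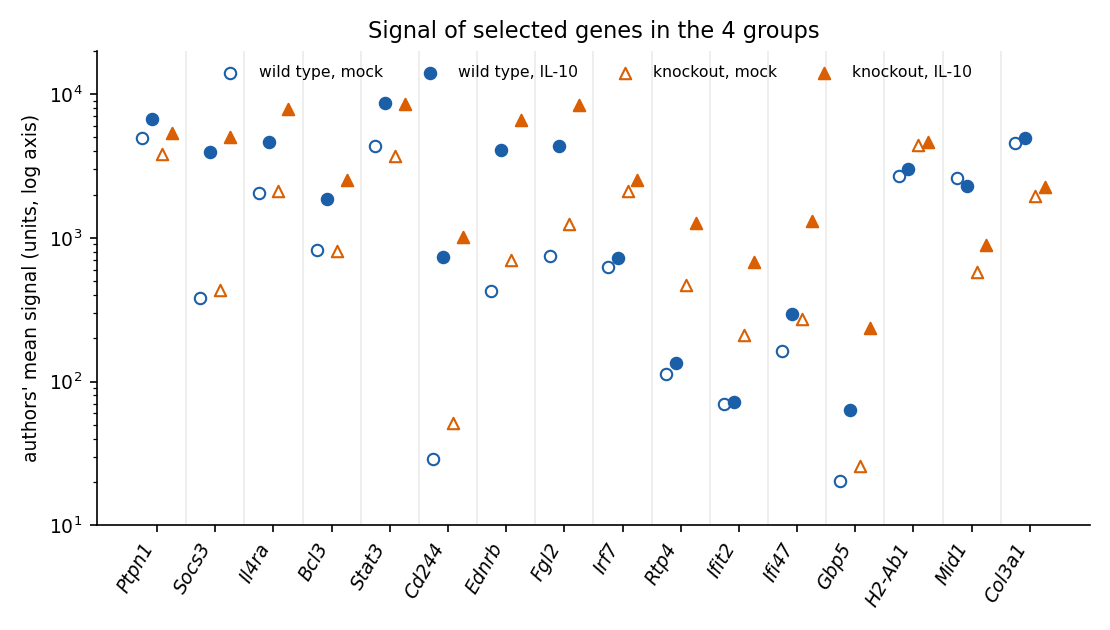
Authors' mean signal (log axis, units of the deposited table) of 16 genes in the 4 groups, 1 symbol per group, circles for wild type and triangles for the knockout, open for mock and filled for IL-10, with no error bars because there is 1 value per group. Irf7 stands at 625 and 718 units in wild type and at 2124 and 2517 in the knockout, while Socs3 differs mainly by treatment.

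With IL-10 the interferon lists also stood higher in the knockout, with larger medians than under mock. Rtp4 was listed at 135 units in wild type and 1274 in the knockout, a log2 ratio of 3.01, and Ifit2 at 72.5 and 675. Ly6a stood at 17 and 254 units, Tgtp2, an interferon-inducible GTPase gene, at 45 and 373, Pydc4 at 17.5 and 208, and Ifit1 at 52 and 345. Of the type I interferon list, 18 of 28 members were at least 2-fold higher, with a median of 1.17, and all 28 were above 0. Of the interferon-gamma list, 7 of 21 were at least 2-fold higher, with a median of 0.70. The monocyte marker median was 0.62 and that of mesothelial and fibroblast markers was -0.54, close to the mock values. The IL-10 and STAT3 list had a median of 0.25, with Il21r at 322 and 785 units and Il4ra at 4637 and 7869. Socs3 had a log2 ratio of 0.35, Bcl3 0.44, Tnf 0.55 and Stat3 -0.03. The list of MHC class II and costimulation genes had a median of 0.32 and the alternative activation list 0.38. Cholesterol synthesis genes were lower, with a median of -0.31 at percentile 0, and all 15 members were below 0, although none reached 2-fold. Their mock median was -0.16. Cell cycle genes had medians of -0.12 under mock and -0.11 with IL-10, and Mki67 stood at 1282 and 913 units with IL-10.

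Lower in the knockout with IL-10 were Lrp1 (196010 and 50969 units), Mid1 (2290 and 887), 9930013L23Rik (350 and 140), Col3a1 (4923 and 2261), the complement receptor gene Vsig4 (518 and 233) and Pkhd1l1 (173 and 69.5). In all, 68 genes were at least 2-fold higher and 9 at least 2-fold lower, or 46 and 3 with a pseudocount of 4 ppm. The differences under both treatments, again from separate columns, had a Pearson's r of 0.73 and a Spearman's rho of 0.68 across genes. Both fell with transcript length, with a Spearman's rho of -0.53 under mock and -0.40 with IL-10. No label used here says whether mock and IL-10 cells came from different mice. Part of the agreement may thus come from shared mice or from that trend. Of the 37 and 68 higher genes 28 were shared, against 0.221 for independent lists, and of the 12 and 9 lower genes 6 were shared, against 0.00947.

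**Figure D3:**
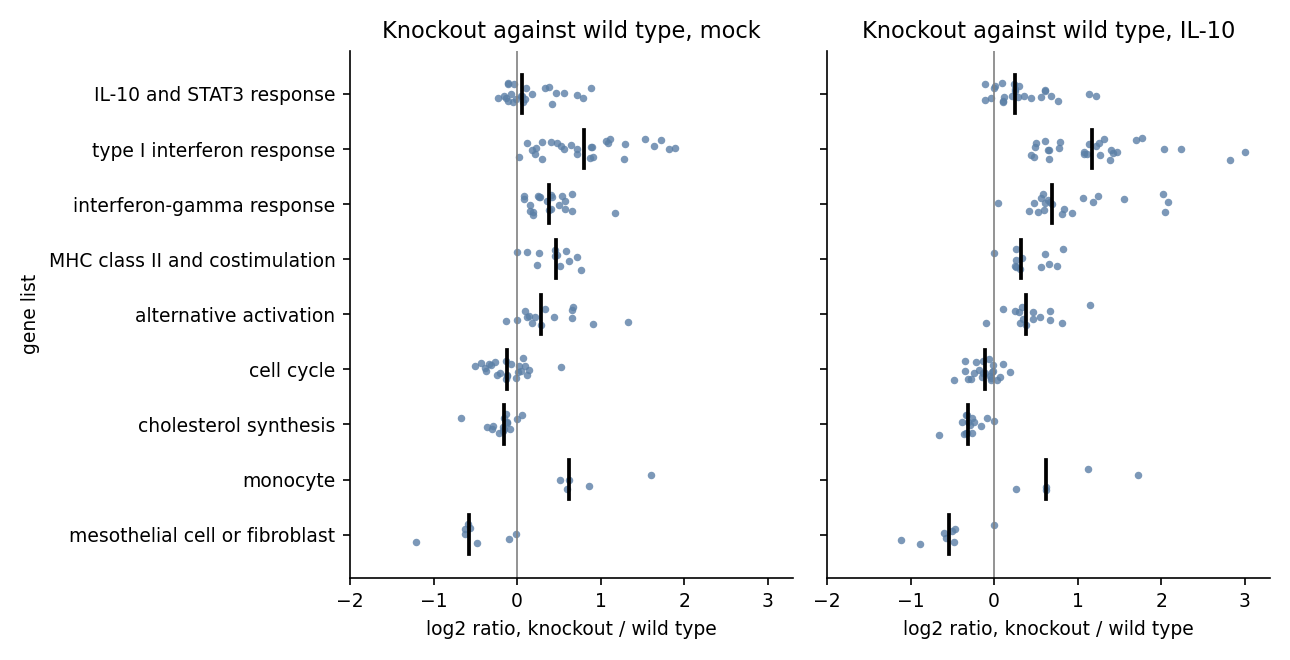
Log2 ratio of knockout to wild-type signal under mock (left) and IL-10 (right) for the kept members of 7 gene lists and 2 cell type marker lists, 1 point per gene, with a bar at each median. The type I interferon medians are 0.80 and 1.17, and the medians of the mesothelial and fibroblast markers are -0.58 and -0.54.

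The difference between the genotypes' IL-10 log2 ratios addresses whether loss of Ptpn1 went with a different response. It was largest for interferon-inducible genes. Tgtp2 was listed at 40 and 45 units in wild type without and with IL-10 and at 98.5 and 373 in the knockout, a difference of 1.57. Ifit2 differed by 1.53, Iigp1 by 1.44, Gbp5 by 1.40 and Ifi47 by 1.39, and Ifi47 stood at 163 and 294 units in wild type and 273 and 1299 in the knockout. Lilrb4, an inhibitory receptor gene above 20000 units, differed by 1.28. Of the 49 kept members of both interferon lists 47 were above 0, with a median of 0.41. The type I list alone had a median of 0.39 and the interferon-gamma list 0.42, each at percentile 100. The 5 monocyte markers had a median difference of 0.03, and 1 of them, Ccr2, lay above 5 ppm.

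The IL-10 and STAT3 list had a smaller median difference of 0.20 at percentile 100, with 20 of 24 members above 0 and none past 2-fold. Il4ra differed by 0.71, Il21r by 0.50, Bcl3 by 0.48, Nfil3 by 0.23, Stat3 by 0.20 and Socs3 by 0.18, whereas Il1rn and Il10ra differed by -0.17 and -0.07. JAK-STAT components had a median of 0.16, with Socs2 at 0.39 and Cish at 0.35. Among 62 genes off the interferon lists whose IL-10 ratio averaged over both genotypes was at least 2-fold, 53 had the larger ratio in the knockout, with a median difference of 0.28. Over all kept genes 48.7% were above 0.

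Downward, the largest differences among genes of at least 5 ppm were in Rps2-ps10 (-1.32), a ribosomal protein pseudogene that can share reads with near-identical copies, Atp5l (-1.05) and the ubiquitin gene Ubb (-1.01). Ubb stood at 26635 and 31177 units in wild type and at 55131 and 31920 in the knockout, so its difference lay in the knockout mock column. Ubb lies above 20000 units, where a small move in rank shifts the signal widely. In all, 11 genes differed by at least 2-fold upward, 5 of them on an interferon list (Ifit2, Iigp1, Gbp5, Ifi47 and Rtp4), and 4 downward. The remaining downward gene, Zhx2 (-1.30), lay below the level for named genes and was picked out after its values were seen. Its row overlaps that of another gene. The count was 19 and 11 with a pseudocount of 0.25 ppm, 5 and 2 with 4 ppm, and 5 and 3 with the filter at 5 ppm.

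No kept member of the lists for the unfolded protein response, immediate early and heat shock genes, glycolysis and hypoxia, or cholesterol efflux and lipid storage reached 2-fold in the IL-10 response. The medians in wild type and knockout were 0.05 and 0.09 for the unfolded protein response (percentiles 87.7 and 99.6; -0.01 and 0.07 with the length trend subtracted), -0.07 and -0.02 for immediate early and heat shock genes, 0.14 and 0.04 for glycolysis and hypoxia (percentiles 99.9 and 93.9), and -0.04 and 0.00 for cholesterol efflux and lipid storage. Scavenger and Fc receptors and complement had medians of 0.16 and 0.04, at percentiles 99.9 and 95.2. Of other cell types, mast cell markers were higher in the knockout in all 4 kept members, with medians of 0.41 under mock and 0.54 with IL-10 at percentiles 99.86 and 99.89. Their signals were low. Under mock Kit stood at 18 units in wild type and 25.5 in the knockout, Cpa3 at 53.5 and 79, Cma1 at 96 and 137.5 and Tpsb2 at 122.5 and 196.5. Below the filter, Tpsab1 stood at 14 and 24.5 and Mcpt4, the other way, at 26 and 18. The mock median of the 4 kept mast cell markers was 0.27 with the trend over transcript length subtracted. B cell markers had a mock median of -0.08 over 3 members, at percentile 30.4, or -0.16 with that trend subtracted. Too few markers were kept for a median elsewhere: among neutrophil markers Retnlg stood at 29.5 units in wild type and 110 in the knockout under mock and S100a8 at 53 and 56.5, the eosinophil marker Siglec5 at 354 and 393, the dendritic cell markers Zbtb46 at 101 and 81 and Cd209a at 6 and 14.5, the T cell markers Lck at 11.5 and 10 and Il7r at 32926 and 37024, and the erythroid marker Hba-a1 at 29 and 18.5. Below the filter, the other listed eosinophil marker, Ccr3, stood at 9 units in wild type and 31.5 in the knockout under mock. Also below it, the neutrophil markers S100a9 and Cxcr2 stood at 8.5 and 15 and at 15 and 18. The T cell marker Cd5 stood at 15.5 and 31 and the erythroid marker Hbb-b1 at 22 and 25, likewise below it. No NK cell marker was listed.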

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

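The tests of transcript length, signal range and monocyte markers reported here were chosen only after the results they bear on were seen. Those of the chromosome 2 segment and of sex were chosen before.

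Rps2-ps10 was the 1 gene of at least 5 ppm whose IL-10 log2 ratios pointed in opposite directions in the genotypes by 0.5 or more each, 0.54 in wild type and -0.78 in the knockout, a difference of -1.32. That difference was not tested, because each group has 1 value. Its related pseudogene Rps2-ps13, named after its value was seen, differed by 1.11 the other way.

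The interferon lists were among the genes whose IL-10 response differed between the genotypes: the 49 kept members of both interferon lists had a median difference in IL-10 log2 ratio of 0.41, larger in the knockout for 47. A difference between columns in how signal depends on transcript length is argued against: once the length trend was subtracted the median was 0.40. An effect of low signal alone is also argued against, since the 21 members with a signal of at least 500 in every column had a median of 0.31, with 20 above 0. A larger share of monocytes in the knockout column with IL-10 cannot be excluded: the 5 markers had a median difference of 0.032, but 1 of them, Ccr2, which macrophages also express, was alone above 5 ppm. Ccr2 rose alike in both genotypes, from 371 to 639 units in wild type and from 582 to 995 in the knockout, a difference of 0.003. Its signal thus differed with treatment, so it cannot measure the share of monocytes apart from IL-10. A monocyte excess alike under both treatments would also leave the marker difference small. The markers' knockout against wild-type medians were 0.61 under mock and 0.62 with IL-10, so such an excess stays open. Genotype, the difference named by the design, may account for the pattern and stays untested without values per sample.

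Of 11400 genes, 172 differed by at least 1.5-fold between genotypes in the same direction under both treatments, 106 higher and 66 lower in the knockout. A broad excess of such genes around Ptpn1, which a donor-strain segment carried with the allele could give, is argued against. Within 20 Mb of Ptpn1, 4 of 253 genes (1.58%, exact 95% interval 0.432 to 4.00%) were of this kind, against 1.51% of the other genes. The interval treats genes as independent. Of the 4, named after their values were seen, Zbp1 and Ctsz were higher and Sulf2 and 5031425F14Rik lower in the knockout. The last was listed at 91 units in wild type and 6.5 in the knockout under mock, and at 40 and 3 with IL-10. Ctsz lies above 20000 units, where rank steps are wide. On mm9 chromosome 2 the rows of Sulf2, 5031425F14Rik, Zbp1 and Ctsz start at 165899650, 166272951, 173032116 and 174253361, and that of Ptpn1 at 167757872. A shorter segment, or an effect on single genes close to Ptpn1, is not excluded. The window holds 253 of the 11400 genes, so the comparison does not show the source of most of the 172. Different sexes are argued against, since the 4 listed Y-linked genes had median absolute log2 ratios of at most 0.085 under either treatment; Xist was not listed. A length trend between columns could account for part: among genes with a known length, the count went from 170 to 132 when it was subtracted, and 119 were in both sets. Other cells in the culture and genotype stay open, the cells because monocyte and mast cell markers were higher (mast cell medians 0.41 under mock and 0.54 with IL-10) and mesothelial and fibroblast markers lower in the knockout. Strain differences elsewhere in the genome, and differences between mice or preparations, were not tested and stay open too. With 2 samples per group and no values per sample they cannot be told apart from genotype.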

How the results depend on the processing

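No paired analysis was possible because the deposited columns carry no replicate. For the same reason limma fits, calcNormFactors scaling, robust and weighted fits, fits of 4 libraries, count models, correlation and rotation tests of lists, and the leaving out of each library were not run. The limit of 1.5-fold, trimmed-mean scaling, subtraction of a length trend, leaving out genes above 20000 units and leaving out cell markers were chosen after seeing the data. With no replicates, a list median was taken as moved at 0.1, a named gene at 0.2 and a count beyond 1.5 times; these bounds are conventions.

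Counts of genes past 2-fold stayed within 1.5 times, except as follows. For the genotype difference in the IL-10 response (15 genes), the count was 30 with a pseudocount of 0.25 ppm, 7 with 4 and 8 with a filter of 5 ppm. For knockout against wild type under mock (49 genes) it was 75, 23 and 31 under those settings. For knockout against wild type with IL-10 (77 genes) it was 49 with a pseudocount of 4. These settings act on low genes by construction. A limit of 1.5-fold gave 223 genes for IL-10 in wild type, 356 in the knockout, 323 for the genotypes under mock (163 higher and 160 lower), 318 with IL-10 and 87 for the difference in response, as a lower limit must. With the length trend subtracted the difference in response held 13 genes upward and 2 downward, against 11 and 3 before it among the 11222 kept genes with a known length. The Ptpn1 log2 ratio under mock ranged from -0.39 to -0.33. Of 630 list medians under an alternative 18 moved, and of 2456 values of named genes 88 moved and 0 past 2-fold changed sign. Most settings could not have changed a sign. A pseudocount cannot reverse the ratio of 2 columns, and filters, a fold limit or leaving out genes do not alter a gene's value. No scaling moved the median of all kept genes by 0.1. The equal sums and shared highest value of the columns made that likely beforehand, so it says little about the normalization. Unknown depth, shared highest values and wide rank steps limit the most abundant genes, and the missing spread between samples limits every comparison.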

Other observations

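The gene families and single genes in the next 2 paragraphs were chosen after their values were seen, and their differences were not tested. Among the 49 genes at least 2-fold higher with IL-10 in both genotypes were several outside the fixed lists. The endocytic adaptor gene Dab2 was listed at 2865 and 12436 units in wild type and 3079 and 16015 in the knockout. The nucleoside transporter gene Slc28a2 stood at 933 and 3704 units and at 1447 and 7402, the adenosine receptor gene Adora3 at 37 and 190.0 and at 53 and 374, and Sphk1, which encodes sphingosine kinase 1, at 361 and 1241 and at 497 and 1876. Il13ra1, the partner of Il4ra in the type II IL-4 receptor, stood at 1121 and 3476 units and at 1366 and 4576. The arginase genes Arg1 and Arg2 were both in this set, with Arg2 at 23 and 108 and at 32.5 and 198.

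Between genotypes, the 7 kept Ms4a genes, which encode membrane-spanning proteins, had a median log2 ratio of 1.05 under mock and 0.76 with IL-10, and Ms4a7 stood at 2313 and 6509 units under mock. The 13 kept MHC class I genes had medians of 0.44 and 0.44, although reads of these near-identical genes can be shared among them. The 23 kept collagen genes had medians of -0.55 and -0.48, with Col1a2 at 16470 and 10235 units under mock. After the length trend was subtracted the collagen medians were -0.42 and -0.42. Col1a1 and Col3a1 are also on the list of mesothelial and fibroblast markers, whose medians were -0.58 and -0.54. The collagen values cannot be told apart from a difference in those cells. Among Ly6 genes, Ly6e stood at 3904 and 8533 units under mock.

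Zhx2 was listed at 109, 95, 49 and 1 units in wild type mock, wild type with IL-10, knockout mock and knockout with IL-10. An unnamed gene that overlaps it on the same strand (ENSMUSG00000093496; mm9 chromosome 15, 57527284 to 57594277) was listed at 1, 1, 55 and 116, and both together at 110, 96, 104 and 117. The value of either row alone is uncertain.

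The tests of the next pattern were chosen before their results were seen. Several genes shared the highest signal of a column, 8 in wild-type mock. A quantile normalization within bins of GC content was a candidate source, but 3 of the genes fell into the same GC decile, and the highest and lowest decile medians differed 1.30-fold. Binning by gene length is argued against, with decile medians that differed 2.16-fold. The authors' bins and annotation are not known, so binning by GC content or in another form stays open, and no biological explanation was tested.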
